A study of Homo sapiens with 8 samples.

How the data were processed

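Gene expression was measured in EA.hy926 cells, an endothelial-like line made by fusing human umbilical vein endothelial cells with A549 lung carcinoma cells. Per the labels' protocols, the cells were grown with 10% fetal bovine serum, seeded on 35 mm plates and transfected by lipofection with 10 nM of a control siRNA or of an siRNA against NR2F2, an orphan nuclear receptor also called COUP-TFII. Total RNA was collected 48 h later, and biotin-labelled cRNA was made from 100 ng of it with a 3' in vitro transcription kit, per the labels' protocols. The control siRNA and the NR2F2 siRNA came from different suppliers, per the labels' protocols, and 1 siRNA against the target was used.

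The deposited table holds 1 value per probe set and array on the log2 scale, and the submitters' processing notes name RMA, which corrects background, quantile-normalizes the arrays and summarises the probes of each set, and the Transcriptome Analysis Console. Their versions and the genome build are not given in the sources used here. The deposited log2 values had nearly equal quartiles on all 8 arrays, and medians ran from 5.45 to 5.50. No further normalization was applied to them, so every value depends on the authors' assumption that the arrays share 1 overall distribution. Arrays carry no count depth, and with 4 arrays per group their number limits the precision.

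Of 49372 probe sets, 79 were array controls, 45278 had 1 gene symbol, 1333 had several and 2682 had no symbol listed. Gene symbols came from the platform annotation supplied with the series, and 45208 of the single-symbol probe sets were matched by Entrez identifier to a RefSeq gene table of GRCh38.p14, which changed 0 symbols. That table was used for names and for the order of genes along chromosomes, and no coordinates are given because the build of the array annotation is not stated. Each gene was taken from its probe set with the highest mean over the 8 arrays, which left 18244 genes. Probe sets with several symbols or none named no gene. No filter on low values was applied because the table holds no detection calls. The level of the siRNA's own target was not analysed here, so the group labels were not checked against it, and each direction below rests on those labels.

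The arrays were grouped by their titles, 4 control siRNA and 4 NR2F2 siRNA, with 0 unassigned columns. Per the series' design text, the cells were divided into 4 sets, both conditions were run on each set as independent experiments, and the RNA of all samples was handled as 1 batch. The text does not say that an array's number is its set, so the numbers were treated as names and the fit had no block. The pair of groups makes 1 comparison. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), two-sided, with Benjamini-Hochberg adjustment over all 18244 genes and a threshold of 0.05. A fold threshold of 2 was added for large changes. Log2 fold changes are NR2F2 siRNA minus control siRNA, and their errors are the moderated standard errors of limma. Figures were drawn with matplotlib 3.10.9.

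Before the data were examined, 31 gene lists with 866 genes were written from general knowledge, of which 811 genes were measured. They cover endothelial identity and function, signalling, matrix, cell cycle, metabolism, stress, interferon and inflammation, and markers of epithelial, smooth muscle or fibroblast and leukocyte cells. Lists were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists. Beside it, camera with an estimated correlation, the rotation test fry, and an exact two-sided permutation test of each list's mean per array were run. The permutation test has 70 regroupings and a smallest p of 0.0286. Adjusted over the 31 lists, this p cannot fall under 0.05 unless many lists reach it. The genes named in the text were fixed by a rule made before the data were examined. They are the 10 largest rises and 10 largest falls among genes past the threshold whose groups of arrays did not overlap, skipping genes without an official symbol, and up to 2 higher and 2 lower members of each list with the largest change among those past the threshold, or the member with the largest change where none passed. This gave 85 genes, and genes named outside the rule are marked as such.

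A 3'/5' index was computed per array as the mean, over the GAPDH and actin control probe sets, of the 3' minus the 5' log2 signal. Alternatives chosen before the data were examined were the replicate number as a block, median centring, cyclic loess, filters at a mean log2 value of 5 and at the median gene, other rules for a gene's probe set, all probe sets as units, an intensity trend with robust estimation, array weights, a fold threshold of 1.5, other set tests, and fits without each array or each number. The 3'/5' index as a covariate and each gene's dimmest probe set were added after seeing the data. The scripts were tested on simulated data of the same size, 20 sets of 18244 genes in which 200 genes were changed. The fit recovered 57.5% of genes changed by 0.4 on the log2 scale, 95.8% of those changed by 0.8 and 99.9% of those changed by 1.5, with 4.2% of calls false. In the same simulated sets, camera called a list shifted by 0.2 in 100% of sets and an unshifted list in 5%. The simulated genes varied independently, whereas the estimated correlation was 0.522 in the S phase list and 0.468 in the G2/M list. These camera rates therefore hold for uncorrelated genes only.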

Results

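The series compared gene expression in EA.hy926 cells, a hybrid line with endothelial features, after transfection with an siRNA against NR2F2 or a control siRNA. The comparison asks how lowering this nuclear receptor, a regulator of venous endothelial identity, changes the transcriptome of endothelial-like cells, as the title of the series frames it. There were 8 arrays, 4 per condition, which the labels describe as independent experiments on 4 sets of cells, with RNA collected 48 h after transfection. Array medians lay between 5.45 and 5.50 on the log2 scale, and the correlation between any pair of arrays over genes was between 0.994 and 0.998. No pair of arrays held the same value for more than 0.101% of probe sets.

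The arrays parted by siRNA along the first principal component, which held 37.1% of the variance. Control arrays scored from -17.7 to -7.47 on it and NR2F2 siRNA arrays from 9.21 to 13.1, while the next component held 16.9% and mixed the groups. The arrays also differed by group in the ratio of 3' to 5' signal of their control transcripts. The mean 3' minus 5' log2 signal of GAPDH and actin was 0.066 ± 0.065 (SD, n = 4) on control arrays and -0.036 ± 0.032 (SD, n = 4) on NR2F2 siRNA arrays (exact two-sided permutation p = 0.0286, the smallest this design can give). For GAPDH alone the means were 0.098 ± 0.042 and 0.0082 ± 0.027, and for actin alone 0.033 ± 0.089 and -0.080 ± 0.044. Over the 8 arrays the index tracked the median, over 11810 genes, of the contrast between a gene's brightest and dimmest probe set. This 1 relation had Pearson's r = 0.964 (exact permutation p = 0.000124) and Spearman's rho = 0.929 (exact permutation p = 0.00223). Pearson's r was 0.995 without the 2 arrays farthest from the median index, and 0.939 (permutation p = 0.00107) for deviations from the group means. Centred over the arrays for each gene, the median contrast ran from -0.033 on NR2F2 siRNA replicate 4 to 0.039 on control replicate 3 (log2). Single genes may differ by more than this median.

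With NR2F2 siRNA more genes were lower than higher at the probe sets used. Among genes past the threshold with an official symbol, STC1, a secreted glycoprotein hormone, had the largest fall. It went from 9.69 ± 0.095 on control arrays to 7.42 ± 0.090 (SD, n = 4 each), a log2 change of -2.28 ± 0.072 (SE). ITGB8, the beta subunit of an integrin that activates latent TGF-beta, fell by 2.21 on the log2 scale, and TNFSF15, an endothelial cytokine of the TNF family, fell by 2.00. Among the genes that rose, the metabolic kinase RBKS changed by 1.06, the HMG-box factor TOX by 0.98 and S1PR1, the main endothelial receptor for sphingosine-1-phosphate, by 0.88.

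In all, 1081 of 18244 genes (5.93%) passed the limma adjusted threshold, 317 higher and 764 lower, so that 70.7% of them were lower. The median log2 change was 0.36 among the higher genes, or 1.29-fold, and -0.39 among the lower genes, or 1.31-fold. A change of at least 2-fold was seen for 33 genes, 1 higher and 32 lower, and one of at least 1.5-fold for 197 genes, 42 higher and 155 lower. The 4 NR2F2 siRNA arrays all lay on the same side of the 4 control arrays in 1068 of the 1081 called genes and in 13.8% of all genes, against 2.86% by chance. The median log2 change of all genes was -0.0097, and the median SE was 0.080. The share of lower genes depended on the probe set: it was 55.8% (566 higher, 714 lower) with the mean of a gene's probe sets and 46% (375 higher, 320 lower) with the dimmest, the latter chosen after seeing the data. With the 3'/5' index added to the model, also after seeing the data, 213 genes passed, 77 higher and 136 lower, while standard errors were 1.51 times larger.

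**Figure D1:**
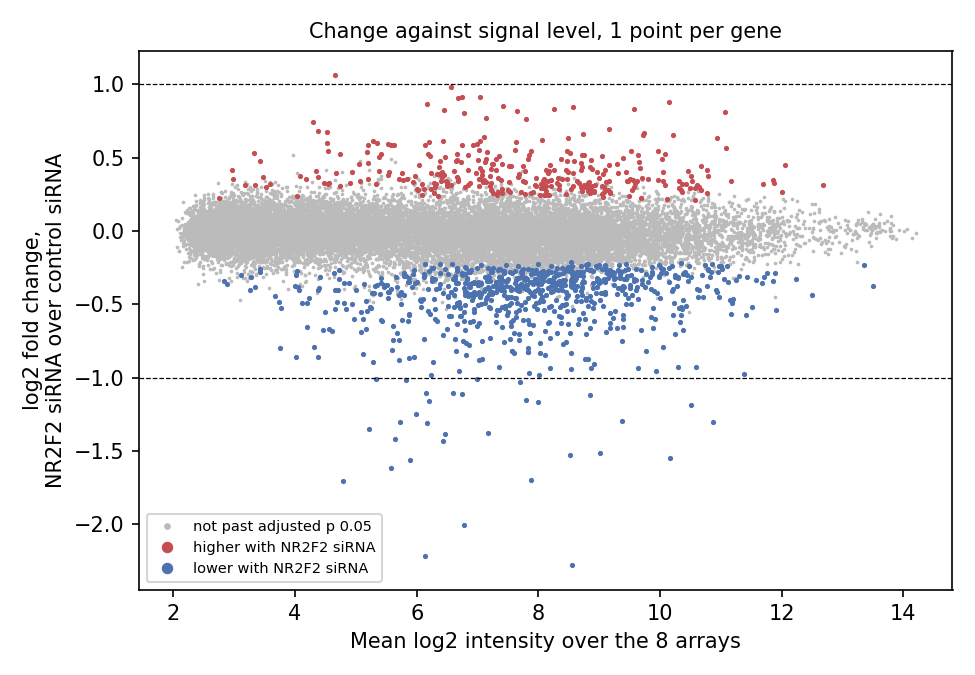
Each point is 1 of 18244 genes, placed by its mean log2 intensity over the 8 arrays (x axis) and its log2 fold change, NR2F2 siRNA over control siRNA (y axis). Red points are the 317 genes that were higher and blue points the 764 that were lower past the adjusted threshold, grey points are the other genes, and the dashed lines mark 2-fold, beyond which lie 1 higher and 32 lower genes.

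The largest falls spanned several functions. Granzyme K (GZMK) changed by -1.71 ± 0.087 (SE), the laminin beta-3 chain LAMB3 by -1.70 ± 0.073, the adaptor protein SH2D1B by -1.62 ± 0.067 and FAM117B by -1.56 ± 0.12. The secreted cystatin CST1 changed by -1.54 ± 0.073, though cystatin genes are near-identical copies that probes can share. NUS1, a subunit of the dolichol-synthesising cis-prenyltransferase, changed by -1.52 ± 0.087, and CSGALNACT2, which starts chondroitin sulfate chains, by -1.51 ± 0.076. Among these 10 genes the limma adjusted p ran from 1.66e-08 for STC1 to 1.85e-05 for FAM117B. At the dimmest probe set FAM117B read 0.18 and did not pass. There ITGB8 (-0.40), LAMB3 (-0.61) and SH2D1B (-0.63) fell less, each still past the threshold.

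The largest rises were smaller than the largest falls. NSUN5, an RNA methyltransferase with near-identical pseudogene copies, changed by 0.91 ± 0.088 (SE), the Notch pathway ubiquitin ligase DTX4 by 0.91 ± 0.096 and the adhesion receptor ADGRG6 by 0.91 ± 0.10. TNFSF18, the ligand of GITR, changed by 0.87 ± 0.13, the interferon-induced gene IFI44L by 0.85 ± 0.14, the lysosomal membrane protein LAPTM5 by 0.84 ± 0.063 and the protease inhibitor SERPINE2 by 0.84 ± 0.071. Of these 10 genes, RBKS had the smallest limma adjusted p, 9.73e-06, and IFI44L the largest, 0.00392. At the dimmest probe set RBKS read -0.077, and TOX (0.19), ADGRG6 (0.19), SERPINE2 (0.23) and IFI44L (0.53) did not pass. Over the 85 named genes, 67 had more than 1 probe set, and in 38 of these the dimmest gave a change smaller by over 1.5 times or of the other sign, among them ECT2 (-0.23), PTGS2 (-0.23), TFPI2 (-0.36), NRP1 (-0.15), TGFBR3 (-0.12) and TPM1 (0.020). Some changes were larger at the dimmest probe set, among them those of DDAH1 (1.07), SPP1 (-1.14), ATP5MC3 (-0.90), DEPP1 (-0.50) and FLRT2 (0.49). Named genes whose dimmest probe set had the opposite sign did not pass there (limma adjusted p of at least 0.497). Among 810 called genes with more than 1 probe set, 0 had a probe set past the threshold in the opposite direction. In the 12 fits that left out arrays, LDHA and MANF passed in 0 and ACAT2 in 1, DEPP1, RELN, PGF and SLC3A2 in 2, FLRT2, ZEB1, SLC7A11 and CD68 in 3, PECAM1 and CCL5 in 4, TLR3 and ESRRA in 5 and HK2 in 6.

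**Figure D2:**
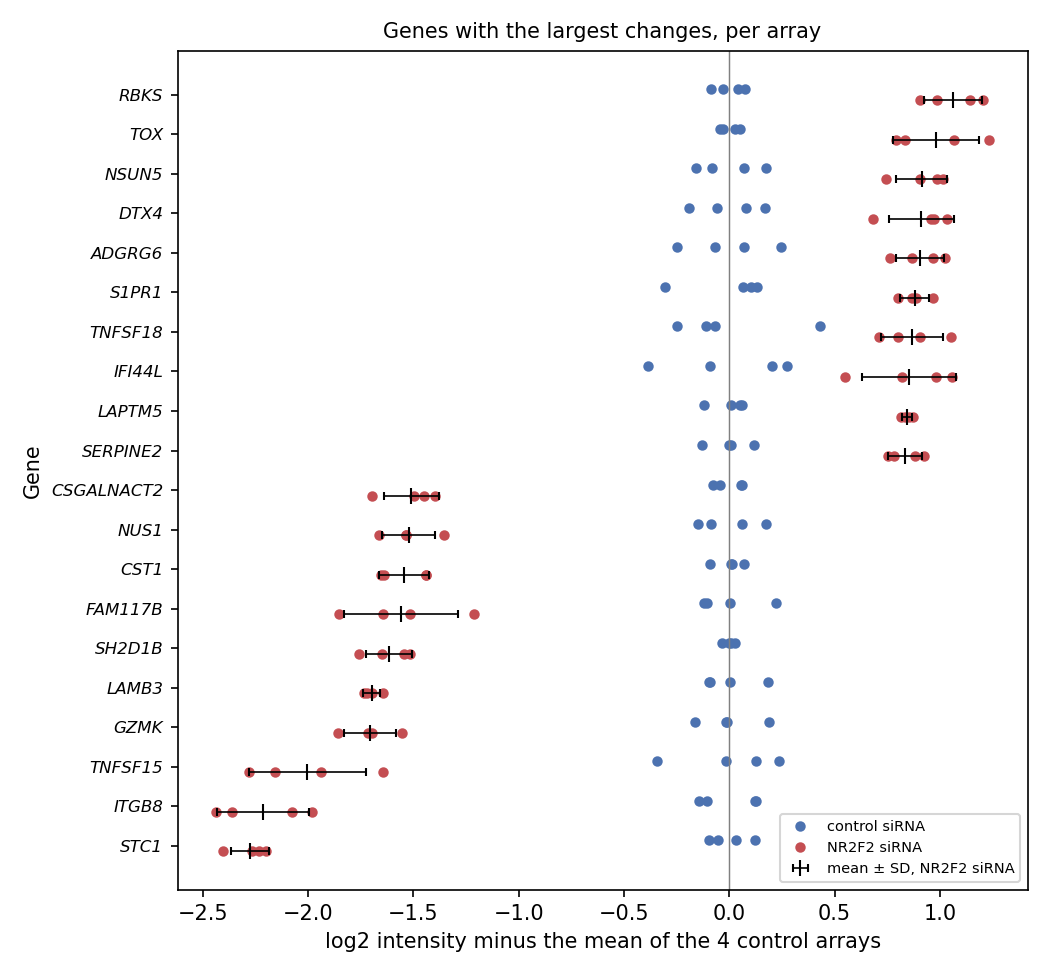
For the 10 genes with the largest rises and the 10 with the largest falls (y axis), each point is 1 array's log2 intensity minus the mean of the 4 control arrays (x axis), blue for control siRNA and red for NR2F2 siRNA, and black bars are the mean ± SD of the 4 NR2F2 siRNA arrays. The means run from -2.28 for STC1 to 1.06 for RBKS, and in each gene the red points lie on 1 side of all the blue points.

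Genes of the cell division cycle were lower with NR2F2 siRNA. Of 39 measured genes of G2/M and mitosis, 16 fell, 1 rose and 22 did not pass, with a mean log2 change of -0.27. The largest falls were those of ECT2, which drives cleavage furrow formation, by -0.60 ± 0.065 (SE), and of the spindle assembly factor TPX2, by -0.58 ± 0.071. CDC25B, a phosphatase that activates mitotic kinases, was the member that rose, by 0.41 ± 0.064. Of 38 measured genes of DNA replication and S phase, 11 fell, 0 rose and 27 did not pass, with a mean of -0.21, and the transcription factor E2F1 changed by -0.52 ± 0.081 and the replication helicase subunit GINS3 by -0.51 ± 0.060. Adjusted over the list alone, 30 G2/M genes and 20 S phase genes fell, with 1 and 0 rising.

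Camera called 5 of the 31 lists at its preset correlation, and 8 of the 35 ways of splitting the 8 arrays into 4 and 4 called as many or more. The camera adjusted p was 4.65e-15 for G2/M and 1.23e-10 for S phase at the preset correlation, and both calls were lost with an estimated correlation, where the adjusted p was 0.836 for each. Before adjustment over the lists, camera with an estimated correlation gave p = 0.0663 for G2/M and 0.128 for S phase. With fry the adjusted p was 0.0264 for G2/M and 0.0568 for S phase. The S phase mean was -0.11 with each gene's dimmest probe set, where that of G2/M was -0.18. The mean of either list was lower on all 4 NR2F2 siRNA arrays than on all 4 control arrays (exact permutation p = 0.0286 for each list, adjusted p = 0.166 over the 31 lists). The unadjusted p is the smallest possible here, so the adjusted p says little about either list. The arrays with the lower lists were also those with the lower 3'/5' index, -0.036 against 0.066. Of 26 measured p53 targets and growth arrest genes 3 fell, among them GDF15 (-0.57 ± 0.086) and the growth arrest gene GADD45A (-0.49 ± 0.058), and 0 rose, with the same counts adjusted over the list alone, a mean of -0.078 and a camera adjusted p of 0.225.

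Interferon-stimulated genes moved the other way. Of 46 measured genes 15 rose, 0 fell and 31 did not pass, with a mean log2 change of 0.21, and adjusted over the list alone 19 rose. IFI44L changed by 0.85 ± 0.14 (SE) and IFI6, an inhibitor of apoptosis and viral replication, by 0.83 ± 0.080. The camera adjusted p was 2.85e-12 at the preset correlation and 0.836 with an estimated correlation, where the unadjusted p was 0.0361. With fry the adjusted p was 0.0264. The mean of the list was higher on all 4 NR2F2 siRNA arrays than on all 4 controls (exact permutation p = 0.0286, again the smallest possible, adjusted p = 0.166). These were again the arrays with the lower 3'/5' index, -0.036 against 0.066.

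Of 19 measured genes of MHC class I antigen presentation 2 rose, the peptide-trimming protease ERAP1 (0.30 ± 0.064) and HLA-E (0.28 ± 0.060), 0 fell, and 4 rose adjusted over the list alone. The mean was 0.079, with a camera adjusted p of 0.0439 at the preset correlation and 0.836 with an estimated one. This call held in 5 of 12 fits that left out arrays, and it was lost with fry (adjusted p = 0.135) and with the dimmest probe set (mean change 0.063, adjusted p = 0.384). Of 20 measured genes of double-stranded RNA sensing 2 rose and 0 fell (3 and 0 adjusted over the list alone). They were the receptor TLR3 (0.53 ± 0.12) and the 2'-5'-oligoadenylate synthetase OAS1 (0.40 ± 0.070), which is also on the interferon-stimulated list. The list mean was 0.094, with a camera adjusted p of 0.0743 at the preset correlation and 0.836 with an estimated one. At the preset correlation it was 0.0333 with the 3'/5' index in the model.

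**Figure D3:**
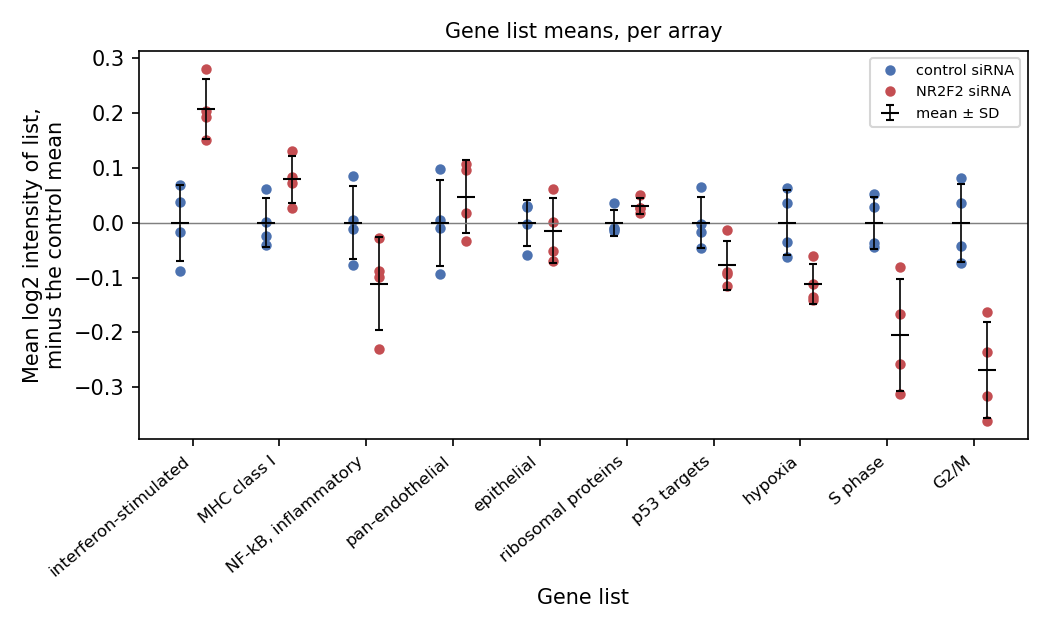
Each point is 1 array's mean log2 intensity over the measured genes of a list (x axis) minus the mean of the 4 control arrays (y axis), blue for control siRNA and red for NR2F2 siRNA, and black bars are the group mean ± SD (n = 4). The NR2F2 siRNA means run from 0.21 for interferon-stimulated genes to -0.27 for G2/M genes, and the ribosomal protein mean is 0.030, with the same sign under each scaling that was run.

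Inflammatory mediators moved in both directions. Of 34 measured NF-kB and inflammatory genes, 4 fell and 2 rose (5 and 3 adjusted over the list alone). The prostaglandin synthase PTGS2 changed by -1.35 ± 0.098 (SE) and the neutrophil chemokine CXCL8 by -0.94 ± 0.16, while TLR3 and the chemokine CCL5 (0.41 ± 0.099) rose. TLR3 is also on the double-stranded RNA sensing list. A dimmer probe set of CCL5 read -0.027. The list mean was -0.11, with a camera adjusted p of 0.486.

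Leukocyte adhesion molecules included some of the larger falls. Of 13 measured genes 3 fell and 0 rose (4 and 1 adjusted over the list alone), among them P-selectin (SELP, -1.42 ± 0.099), which tethers rolling leukocytes, and ALCAM (-0.98 ± 0.064), whose dimmest probe set read 0.13. The mean was -0.20 and the median 0.055, opposite in sign, and the camera adjusted p was 0.315, while fry, which asks whether the genes move on balance in 1 direction, gave an adjusted p of 0.0264.

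Endothelial identity genes changed in both directions. Of 32 measured pan-endothelial genes 4 rose and 3 fell (9 and 7 adjusted over the list alone), with S1PR1 (0.88 ± 0.094) and the vascular lectin CLEC14A (0.52 ± 0.091) higher and endothelial nitric oxide synthase NOS3 (-0.56 ± 0.064) and PECAM1 (-0.45 ± 0.11) lower. Their mean was 0.047, with a camera adjusted p of 0.31 at the preset correlation and 0.931 with an estimated one. At the preset correlation, the list was called higher with the mean of a gene's probe sets (adjusted p = 0.0194), the probe set of largest variance (0.0241) and the dimmest (0.000379). Of 10 measured venous genes 1 rose, FLRT2 (0.32 ± 0.076), and 2 fell, SELP and EPHB4 (-0.51 ± 0.083), the ephrin receptor of veins (3 and 3 adjusted over the list alone). Their mean was -0.12 and their median 0.052, with a camera adjusted p of 0.786.

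Of 29 measured arterial and Notch genes 1 rose, the BMP9 receptor ACVRL1 (0.69 ± 0.070), and 2 fell, the semaphorin and VEGF co-receptor NRP1 (-0.83 ± 0.078) and DEPP1 (-0.29 ± 0.072). Adjusted over the list alone the counts were 1 and 3, with a mean of -0.032 and a camera adjusted p of 0.786. Of 14 measured lymphatic genes RELN fell (-0.31 ± 0.074) and 0 rose (4 and 1 adjusted over the list alone), with a mean of -0.069 and a camera adjusted p of 0.587.

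Of 29 measured genes of vascular tone, clotting and fibrinolysis 6 fell, among them PTGS2 and the serine protease inhibitor TFPI2 (-1.31 ± 0.095), and 1 rose, DDAH1 (0.40 ± 0.077), which degrades an inhibitor of nitric oxide synthases (6 and 4 adjusted over the list alone). Their mean was -0.10 with a camera adjusted p of 0.498. Of 31 measured angiogenic factors and receptors 4 fell and 2 rose (5 and 2 adjusted over the list alone), with VEGFA (-0.63 ± 0.078) and NRP1 lower and ephrin-A1 (EFNA1, 0.47 ± 0.072) and placental growth factor (PGF, 0.34 ± 0.089) higher. Their mean was -0.042, their median 0.016 and the camera adjusted p 0.832. The dimmest probe set of VEGFA read 0.13.

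In TGF-beta and BMP signalling, 6 of 37 measured genes fell and 3 rose (8 and 3 adjusted over the list alone). The co-receptor TGFBR3 (-0.77 ± 0.072) and ID2 (-0.67 ± 0.12), an inhibitor of bHLH factors, were lower, and ACVRL1 and the inhibitory SMAD7 (0.61 ± 0.10) were higher, with a mean of -0.040 and a camera adjusted p of 0.723. In Wnt signalling, 4 of 42 fell and 2 rose, with the same counts adjusted over the list alone. The receptors FZD4 (-0.70 ± 0.071) and FZD8 (-0.64 ± 0.074) were lower, and the antagonist DKK1 (0.82 ± 0.074) and ROR1 (0.43 ± 0.073) were higher, with a mean of 0.0036 and a camera adjusted p of 0.51.

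Of 49 measured matrix genes 5 fell, among them LAMB3 and COL13A1 (-1.25 ± 0.094), and 1 rose, the collagen IV chain COL4A2 (0.39 ± 0.084), with 6 and 4 adjusted over the list alone, a mean of -0.077 and a camera adjusted p of 0.786. Of 33 mesenchymal genes 3 fell, with the transcription factors ZEB1 (-0.33 ± 0.076) and SNAI1 (-0.32 ± 0.069) among them, and tropomyosin TPM1 rose by 0.56 ± 0.061 (5 and 1 adjusted over the list alone). Their mean was -0.028, their median 0.00079 and the camera adjusted p 0.786. Of 20 osteogenic genes osteopontin (SPP1) fell by 0.47 ± 0.061 and 0 rose, with the same counts adjusted over the list alone. Their mean was -0.0080 while camera ranked them upward, at an adjusted p of 0.936.

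Of 23 measured hypoxia response genes 3 fell, among them VEGFA and adrenomedullin (ADM, -0.42 ± 0.068), and the glucose transporter SLC2A1 rose by 0.55 ± 0.076 (5 and 1 adjusted over the list alone). The mean was -0.11, with a camera adjusted p of 0.0439 at the preset correlation and 0.836 with an estimated one. This call held in 5 of 12 fits that left out arrays, and it was lost with the 3'/5' index in the model (adjusted p = 0.493), with the mean of a gene's probe sets (mean change -0.045, adjusted p = 0.388), with the probe set of largest variance (-0.024, 0.776) and with the dimmest (-0.042, 0.406).

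Of 21 glycolysis genes 2 rose, SLC2A1 and hexokinase HK2 (0.34 ± 0.074), and LDHA fell by 0.23 ± 0.061, a call lost whenever an array was left out (3 and 1 adjusted over the list alone), with a mean of 0.042 and a camera adjusted p of 0.31. At the preset correlation, the glycolysis list was called higher with the mean of a gene's probe sets (adjusted p = 0.0467) and with the probe set of largest variance (0.0241). With an estimated correlation and the main probe sets the camera adjusted p was 0.836. The dimmest probe set of SLC2A1 read -0.12. Of 34 oxidative phosphorylation genes ATP5MC3, a subunit of ATP synthase, fell by 0.48 ± 0.060 and 0 rose, with the same counts adjusted over the list alone, a mean of 0.0014 and a camera adjusted p of 0.587. Of 30 fatty acid genes the fatty acid carrier FABP4 fell by 1.01 ± 0.069 and 0 rose, with the same counts adjusted over the list alone. Their mean was -0.0056 and their median 0.030, with a camera adjusted p of 0.587. Of 24 cholesterol genes the efflux pump ABCA1 rose by 0.54 ± 0.088, with -0.10 at its dimmest probe set, and ACAT2 fell by 0.29 ± 0.077, with the same counts adjusted over the list alone. Their mean was 0.021 and their median -0.031, with a camera adjusted p of 0.638.

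Stress responses were divided. Of 33 unfolded protein and amino acid response genes 2 rose, both chains of the cystine transporter, SLC3A2 (0.34 ± 0.083) and SLC7A11 (0.29 ± 0.066), and 2 fell, DNAJC3 (-0.49 ± 0.085) and MANF (-0.24 ± 0.064), with 2 and 5 adjusted over the list alone, a mean of -0.061 and a camera adjusted p of 0.269. Of 29 NRF2 and antioxidant genes 3 fell and 1 rose, with the superoxide-forming oxidase NOX4 (-0.98 ± 0.086) and the reductase AKR1B10 (-0.62 ± 0.070) lower and SLC7A11 higher (3 and 4 adjusted over the list alone). Their mean was -0.0022 and their median 0.037, with a camera adjusted p of 0.31. Among 33 other nuclear receptors and partners the retinoic acid receptor RARB fell by 0.84 ± 0.090 and ESRRA rose by 0.34 ± 0.077 (1 and 3 adjusted over the list alone), with a mean of 0.016 and a camera adjusted p of 0.486.

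Markers of other cell types did not pass as lists. Of 35 epithelial genes, which mark the A549 parent, AKR1B10 and claudin-1 (CLDN1, -0.58 ± 0.093) fell and 0 rose (2 and 1 adjusted over the list alone). Their mean was -0.015 while camera ranked them upward, at an adjusted p of 0.786, and the dimmest probe set of CLDN1 read 0.20. Of 20 smooth muscle and fibroblast genes RGS5 (-0.93 ± 0.069) and smoothelin (SMTN, -0.44 ± 0.094) fell and 0 rose, with the same counts adjusted over the list alone, a mean of -0.060 and a camera adjusted p of 0.786. The dimmest probe set of SMTN read 0.14. Of 19 leukocyte genes CD68 fell by 0.32 ± 0.078 and 0 rose (2 and 0 adjusted over the list alone), with a mean of -0.027, camera ranking upward and an adjusted p of 0.985. Of 34 ribosomal protein genes 0 rose and 0 fell in limma over all genes and over the list alone, and 1 was higher at an unadjusted p under 0.05. The largest change was that of RPL7, 0.17 ± 0.066, with a limma adjusted p of 0.195. The list mean was 0.030, with a camera adjusted p of 0.127 at the preset correlation and 0.836 with an estimated one. At the preset correlation it was 0.0456 with the mean of a gene's probe sets and 0.0223 with an intensity trend and robust estimation.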

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

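The 3'/5' index was chosen as a measure after the data were seen; the gene lists and the rule for outlying arrays were fixed before. Within each group of 4 arrays, an array counted as outlying when its distance to the nearest other array made up more of the group's range than Dixon's 95% critical value allows, and this ratio is given for each. Of 236 groups of values examined, 11 had such an array, against 11.8 expected by chance.

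Among the named genes, S1PR1 had a low value on control replicate 3, 9.41 against a mean of 9.81 on the others (ratio 0.845). On NR2F2 siRNA replicate 2, ALCAM read 10.78 against 10.94 (ratio 0.955), and on NR2F2 siRNA replicate 3 NRP1 read 8.05 against 8.15 (ratio 0.912). FZD4 read 9.03 against 9.16 on control replicate 2 (ratio 0.833), and SLC2A1 read 8.03 against 8.26 on control replicate 4 (ratio 0.84). Control replicate 3 was high for FABP4, 7.64 against 7.46 (ratio 0.838), and for DNAJC3, 7.96 against 7.75 (ratio 0.876). Each of these genes passed the limma threshold in the same direction in all 12 fits that left out arrays.

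Among the list means, leukocyte adhesion genes were low on NR2F2 siRNA replicate 4, 7.40 against 7.51 (ratio 0.855). Unfolded protein response genes were high on NR2F2 siRNA replicate 1, 9.18 against 9.11 (ratio 0.947), and ribosomal protein genes on control replicate 1, 13.28 against 13.23 (ratio 0.912). The 3'/5' index was low on NR2F2 siRNA replicate 4, -0.085 against -0.020 on the other arrays of its group (ratio 0.929).

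Probe sets with no symbol listed stood outside the gene comparison. Tested in the limma fit of all 49293 non-control probe sets, 144 of these 2682 passed the adjusted threshold, 60 higher and 84 lower, or 5.37% against 5.82% of all probe sets. Their log2 changes ran from -2.97 to 0.88, and 8 were at least 2-fold lower.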

How the results depend on the processing

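The fits with the 3'/5' index and with each gene's dimmest probe set were chosen after the data were seen; all others were fixed before. The target's own level was not analysed here, so none was run for it, and the pseudocount alternatives were not run because the values were already on the log2 scale. Arrays give no counts, so signal over background limits dim genes, and the table holds no detection calls.

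The count of 1081 genes became 1649 among genes with a mean of at least 5, 1753 among genes above the median level, 1896 with an intensity trend and robust estimation, 2869 when all probe sets were counted, 695 with the dimmest probe set and 213 with the 3'/5' index, of which 203 were shared with the 1081, all in the same direction. It was 742 to 897 without 1 array and 579, 623, 533 and 650 without replicates 1, 2, 3 and 4 of both groups, where fewer arrays entered, so that the range was 533 to 897. The count of 33 genes at 2-fold became 19 with the mean of a gene's probe sets, 19 with the dimmest, 77 over all probe sets and 197 at 1.5-fold, and was 31 to 37 with arrays left out. The share of lower genes was 52% (684 higher, 742 lower) with the probe set of largest variance and 51.3% (1397 and 1472) over all probe sets. The cause of the other differences was not tested.

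The 5 lists called by camera became 3 at a mean of at least 5, 3 among genes above the median level, 3 with array weights, 3 with fry and 0 with an estimated correlation, where 1 list was at an unadjusted p under 0.05. They were 3 to 5 with arrays left out, 3 without NR2F2 siRNA replicate 2 or 4. Interferon-stimulated, G2/M and S phase genes passed in all 12 fits with arrays left out, but S phase genes did not with fry (0.0568), and with the dimmest probe set the S phase mean was -0.11 and the G2/M mean -0.18, both still called. The MHC class I call was lost without control replicate 2 (adjusted p = 0.108) or 4 (0.0947) and without NR2F2 siRNA replicate 1 (0.0624), 2 (0.0739) or 4 (0.0797), and also at a mean of at least 5 (0.0628), above the median level (0.078) and with array weights (0.0523). The hypoxia call was lost without control replicate 1 (0.111) or 3 (0.109) and without NR2F2 siRNA replicate 2 (0.0739), 3 (0.106) or 4 (0.0743). It was also lost with cyclic loess (0.0557), at a mean of at least 5 (0.196), above the median level (0.213), with array weights (0.0598) and with fry (0.0943). At the preset correlation, pan-endothelial genes were called higher with the mean of probe sets (0.0194), the largest variance (0.0241) and the dimmest (0.000379). Glycolysis genes were so called with the mean of probe sets (0.0467) and the largest variance (0.0241), and ribosomal protein genes with the mean of probe sets (0.0456) and the intensity trend (0.0223). The mean of probe sets thus called 7 lists, 5 of them higher. Double-stranded RNA sensing genes were called, also at the preset correlation, without control replicate 1 (0.0391), NR2F2 siRNA replicate 3 (0.0329) or both replicates 3 (0.0261).

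With the replicate number as a block, 984 genes (300 higher, 684 lower, 880 of them shared), 33 genes at 2-fold and 5 lists passed. Same-numbered arrays deviated together with correlations of 0.22, 0.097, -0.057 and -0.019, and 2 of 4 correlated best with their own number. Some list means, such as that of NF-kB genes, fell with the number in both groups, and others, such as oxidative phosphorylation, did not. Whether the numbers mark the sets of cells therefore stays open. If they do, the main fit, the permutation tests and the splits left out a pairing.

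Of the 84 named genes with a call, 65 kept it without any 1 array and 61 also without any number. Without control replicates 1, 2, 3 and 4 in turn 9, 13, 13 and 11 lost it, and without NR2F2 siRNA replicates 1, 2, 3 and 4 in turn 15, 13, 11 and 11. With the 3'/5' index 32 lost it and 52 kept it. With the replicate block 7 lost it and 77 kept it, with the mean of probe sets 6 lost it and 78 kept it, and with array weights 2 lost it and 82 kept it. With the probe set of largest variance 75 kept it, 8 lost it in the same direction and CCL5 reversed to -0.027. With the dimmest probe set 44 kept it, 31 lost it in the same direction and 9 reversed without passing. They were CCL5 (-0.027), RBKS (-0.077), FAM117B (0.18), ALCAM (0.13), VEGFA (0.13), ABCA1 (-0.10), SLC2A1 (-0.12), CLDN1 (0.20) and SMTN (0.14). No named gene reversed in the remaining alternatives.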

Other observations

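The fits with other normalizations and without single arrays were fixed beforehand, but their use as tests of the patterns here, the tests of p53 targets, NF-kB genes and off-target silencing, the fits with the 3'/5' index and the dimmest probe sets, and the gene family tests were chosen after the results were seen, and the tests of neighbouring genes after the called genes were seen.

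Called genes lay side by side along chromosomes more often than permuted calls. Of 18175 adjacent pairs of measured genes, 67 were both called in the same direction, 9 both higher and 58 both lower, against a mean of 40.5 over 10000 permutations within classes of equal signal (p = 1e-04, the smallest these can give), and 16 were called in opposite directions against 28.6 (permutation p = 0.0062). The following examples were chosen after their values were seen. A run of 4 lower neighbours was CCDC190 (-0.79), the G-protein regulators RGS4 (-1.30) and RGS5 (-0.93), and the kinetochore gene NUF2 (-0.51). PTGS2 (-1.35) lay beside the phospholipase PLA2G4A (-0.44), which releases its substrate, and osteopontin (SPP1, -0.47) beside ABCG2 (-0.61) and PPM1K (-0.60). Pairs that rose together were the caspase CASP1 (0.61) and CARD16 (0.54), IFITM1 (0.64) and IFITM3 (0.33), and GBP1 (0.51) and GBP3 (0.39). Whether probes are shared within these pairs was not checked.

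Among 324 groups of genes that share a symbol root, 2 passed camera's adjusted threshold. Of 36 centrosomal CEP genes, 31 had a negative change and 3 fell, CEP126 (-1.10), CEP55 (-0.43) and CEP15 (-0.24). The mean was -0.16 (camera adjusted p = 0.00142, and 0.988 with an estimated correlation). On the cell-cycle lists there are 0 of them, but those lists are short, so this does not set them apart from cell division genes. The CEP mean was -0.17 under median centring and under cyclic loess. It was -0.058 with 19 negative when the 3'/5' index was in the model and -0.063 with 20 negative at the dimmest probe set. All 9 TCEAL genes had a negative change and 3 fell, TCEAL3 (-0.46), TCEAL6 (-0.40) and TCEAL1 (-0.38), with a mean of -0.20 (adjusted p = 0.0455, and 0.988 with an estimated correlation) and of -0.14 with 8 negative when the index was in the model.

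The grouping by siRNA gave 1081 genes past the limma threshold and 33 at 2-fold, and the highest of the other splits gave 0 in each case. So 1 of the 35 splits of the 8 arrays, the real one, reached each count, the smallest share possible here. Every other split mixes the siRNA groups, which puts the group difference into its error and lowers its count. The splits therefore do not exclude chance, and any other difference between the groups would give the same counts. For the count of 5 lists called by camera, 8 of the 35 splits gave as many and the highest other split gave 9, so chance may account for that count.

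The first pattern is the excess of falls. Normalization stays open as a source, because median centring and cyclic loess, which left at least 70.7% of called genes and 32 genes at 2-fold lower, moved the median of all genes by at most 0.012 on values that were already quantile-normalized. The difference in 3'/5' signal may account for the share of falls among all called genes. That share was 46% with the dimmest probe sets and 63.8% with the index in the model. The 32 genes at least 2-fold lower had a median change of -1.22 with the index in the model and -1.31 without it. Of them, 100% kept a 95% interval below 0. With the index, 26 lower and 6 higher genes passed at 2-fold. However, these 32 genes were picked for large falls in the same data. The index also parted the groups, from 0.0078 to 0.156 on control arrays and from -0.085 to -0.017 on NR2F2 siRNA arrays. This fit therefore cannot fully separate the 3'/5' difference from the siRNA, and the 3'/5' difference stays open for the large falls too. For 24 of these 32 genes with more than 1 probe set, the median was -0.66 at the dimmest probe set against -1.30, with 21 negative and 6 still 2-fold lower, and whether 3'/5' signal or low signal made these changes smaller was not tested. Off-target silencing stays open for these falls because 1 siRNA against the target was used, and these data cannot separate it from lowered NR2F2 itself, the biological explanation the design names.

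The second pattern is the opposite movement of cell-cycle and interferon-stimulated genes. No 1 array accounts for it. With any array left out, the cell-cycle lists kept at least 82% of their mean change and the interferon list at least 85.5%. With the 3'/5' index in the model the change was -0.25 (95% interval -0.49 to -0.010) for the 77 cell-cycle genes. For the 46 interferon genes it was 0.27 (0.12 to 0.43). These changes did not shrink with the index. With the dimmest probe sets, though, the S phase mean was -0.11 and the G2/M mean -0.18, against -0.21 and -0.27. All control arrays had a higher index than all NR2F2 siRNA arrays, so the fit cannot fully separate the 3'/5' difference from the siRNA. The 3'/5' difference therefore stays open for this pattern. Growth arrest through p53 would raise its targets, but these changed by -0.078 (95% interval -0.16 to 0.0014), with 0 called higher and 3 lower. For these 26 genes as a set, the values argue against it. Sensing of transfected RNA could not be settled. The NF-kB genes, which such sensing would also raise, changed by -0.11 (95% interval -0.24 to 0.021). The double-stranded RNA sensing list, which shares OAS1 with the interferon list, changed by 0.094 (camera adjusted p = 0.0743 at the preset correlation). Loss of NR2F2, and the sequence or supplier of its siRNA, stay open as untested explanations.

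The third pattern is the clustering of called genes among neighbours. The permutations moved calls among genes as if genes varied independently, so their p does not measure the spread between arrays. Neighbours whose levels vary together would give such pairs with any difference between the groups. Signal shared between gene copies with like symbols does not account for the whole of the clustering. Without pairs whose symbols share a root, 55 pairs against 38.9 remained (permutation p = 0.0063). Copies with unlike symbols would stay in this count, so shared signal is not excluded as a part of it. Gene span and signal level together do not account for the clustering (permutation p = 2e-04). The 3'/5' difference stays open, since the index parted the groups. With the index in the model, the calls gave 6 pairs against 1.45 (permutation p = 0.004), but these pairs were few and gene copies were not removed. The calls at 1.5-fold gave 7 pairs against 1.51, a ratio of 4.64 (permutation p = 9e-04), but a fold threshold does not remove a 3'/5' difference. A shared regulatory region around some of these genes may be lost with NR2F2, which is a hypothesis that binding data, not used here, would have to test.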
